A study of Mus musculus with 6 samples.

How the data were processed

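Total RNA from 6 cultures of the mouse melanocyte line melan-a was amplified with a 3' in vitro transcription kit and hybridised to Affymetrix mouse arrays with 1 colour, 1 array per group, per the labels' protocols. The deposited values are signal intensities on a linear scale, made with the MAS5 algorithm in Affymetrix Expression Console 1.1 per the submitters' processing notes. Tested on the values, each array's mean without its highest and lowest 2% was 500, so the arrays came scaled to a common level. No detection calls were used here. Array groups were taken from the labels: BRAF-off, BRAF-on, and BRAF-on with ZEB2, SNAIL2, TWIST1 or ZEB1.

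Each array held 45101 probe sets, of which 64 were controls. Of the other 45037, 34945 were paired with 1 gene symbol by the platform annotation, 932 with several and 9160 (20.3%) with none, and only the first kind was used. Symbols were checked through the Entrez number against a RefSeq gene table of assembly GRCm38.p6, which held 34741 of the 34945. This table served for names and for which genes neighbour each other, and no coordinates are given. Of the 18193 genes, 9010 had several probe sets, and a gene's value was that of its probe set with the highest mean log2 signal over the 6 arrays.

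The log2 of the deposited signal was used without further normalization. A floor was set at the median of all values without the control probe sets, 63.7 signal units, and values under it were raised to it. A gene entered a comparison where at least 1 of its 2 arrays reached the floor, and it was counted as higher or lower by size alone, at a ratio of at least 2-fold. With 1 array per group there is no estimate of spread, so no test was run. Comparisons were BRAF-on against BRAF-off and each added factor against BRAF-on. Signals of a dim probe set vary more than those of a bright one, so folds of dim genes are the less certain ones.

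Before the data were examined, 25 gene lists were written down, with 687 of their 745 entries named by a probe set. A list's median log2 ratio was placed among the medians of 10000 random lists of the same size, matched on mean level in 20 bins, and was said to stand apart under the 2.5th or over the 97.5th percentile, as a description of these arrays. The rule for genes named in the text was also fixed then. It takes the 10 largest log2 ratios in each direction among genes measured on both arrays and the 5 largest bounds in each direction, leaving out clone and model names and genes with a measured probe set of the opposite sign. It also takes list members at least 2-fold apart, or up to 4 by size where none is, all introduced factors, and up to 5 genes per direction and factor among BRAF-responsive genes moved back by at least 2-fold. Pax3, Sox10 with TWIST1, Adam8 with ZEB1, Cdh1, the second Snai2 probe set, Pdgfra, Thy1 and Col1a2 with TWIST1, and the neighbours of Tmsb4x fall outside that rule and were named after their values were seen.

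Overlaps between comparisons that share BRAF-on were set beside the overlap of independent lists and beside 100 simulations of unchanged arrays. The simulated spread by level came from the pair of arrays with the fewest genes 2-fold apart, BRAF-off and the array labelled ZEB2. By the SD of log2 ratios, BRAF-off and BRAF-on differed slightly less (0.289 against 0.301). The pair used differs in BRAF activation too, so its spread can hold real differences and overstate the noise. The counting by size was tested on simulated arrays with 200 changed genes for each of the 5 comparisons. Of 50 genes changed 2-fold per comparison, 40 to 60% were called, and all of those changed 4-fold, 8-fold or 16-fold were, among 11439 to 11482 genes entered. In those simulations 126 to 166 unchanged genes per comparison were called too. By construction they return about as many genes as the pair that gave the spread had apart (149). They therefore cannot tell how many of the 159 genes counted for BRAF activation are noise. Of 200 simulated unchanged lists 11 stood apart, and of 50 lists shifted by a log2 ratio of 0.5 all 50 did, in a simulation of BRAF-on against BRAF-off with 18193 genes. Noise was drawn there for each gene alone, so lists whose genes move together were not covered.

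Of the alternatives tried, 9 were fixed before the data were examined: quantile normalization, centring, floors at the 60th and 75th percentile, no floor, the floor as a pseudocount, the median of all probe sets of a gene, leaving out probe sets that match several transcripts, and 3-fold as the size that counts. The comparison of each factor with BRAF-off was added after seeing the data. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.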

Results

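Gene expression was measured in melan-a cells, a line of immortal mouse melanocytes (pigment cells), on 6 oligonucleotide arrays. The cells carried delta-BRAF-ER, an activated form of the kinase BRAF that tamoxifen switches on. The labels give 6 groups with 1 array each: BRAF not activated (BRAF-off), BRAF activated (BRAF-on), and BRAF activated together with ZEB2, SNAIL2, TWIST1 or ZEB1. These 4 proteins are transcription factors of embryonic development known for repressing epithelial genes. Since no group had a second array, no difference was tested and no p-value is given: every fold describes 2 arrays, and their number limits the precision. Of 18193 genes with a probe set, between 10611 (BRAF-off) and 11269 (array labelled ZEB1) lay at or above the floor of 63.7 signal units, and the genes compared below had at least 1 of their 2 arrays there. A fold with 1 array under the floor is given as a lower bound.

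No probe set for the 4 added factors was 2-fold higher on the array labelled with that factor than in BRAF-on. Snai2 was at a signal of 4175 in BRAF-on and 3142 in the array labelled SNAIL2, and a second Snai2 probe set was at 1157 and 407. Zeb2 was at 806 in BRAF-on and 1132 in the array labelled ZEB2, a log2 ratio of 0.49. Its other probe sets were also higher there than in BRAF-on, by 1.15-fold, 1.24-fold, 1.45-fold and 1.70-fold. The 1.45-fold and 1.70-fold ones were highest there of all 6 arrays, the other ones on that labelled TWIST1 (787 and 729). Zeb1 was at 134 in BRAF-on and 109 in the array labelled ZEB1, and Twist1 was at 338 in BRAF-on and 278 in the array labelled TWIST1. Over all 6 arrays both Snai2 probe sets were lowest on the array labelled SNAIL2 and highest on that labelled TWIST1 (4946 and 1735), Twist1 was highest on that labelled ZEB1 (404), and the probe sets used for Zeb2 and Zeb1 were highest on that labelled ZEB2 (Zeb1 168). Braf itself was at 758 in BRAF-off and 687 in BRAF-on. Probe sets on this kind of array lie near the 3' end of the cellular transcript, and where the introduced sequences lie relative to them is not given in the sources used here, so these values do not settle whether the labels are right. The arrays are therefore named by their labels throughout, and "with SNAIL2" and the like stand for the array so labelled.

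The first comparison set BRAF-on against BRAF-off, without an added factor. No array is labelled as tamoxifen without the construct. An effect of the drug itself, or a difference between cultures, therefore cannot be told apart from BRAF activation. Genes for secreted proteases stood out on the higher side. Mmp10, a stromelysin, was at least 40.9-fold higher in BRAF-on than in BRAF-off, Serpinb2, an inhibitor of plasminogen activators, at least 20.6-fold, the collagenase gene Mmp1a at least 14.8-fold and the fatty acid binding protein gene Fabp4 by a log2 ratio of at least 3.91. Mmp13, another collagenase gene, was 7.94-fold higher, Csn3 (a milk casein) 6.73-fold and Gch1, which encodes the first enzyme of tetrahydrobiopterin synthesis, 5.77-fold. On the lower side stood the potassium channel gene Kcnj13 (3.45-fold), Six5 (3.14-fold), the proteoglycan gene Bcan (3.02-fold) and Nrxn3 (at least 3.64-fold). In all, 116 of 11200 genes were at least 2-fold higher and 43 were at least 2-fold lower. Of the 116, 83 (71.6%) lay above BRAF-off on all 5 activated arrays, against 22.8% of all genes higher in BRAF-on. Of the 43, 9 (20.9%) lay below BRAF-off on all 5, against 15.7% of all genes lower in BRAF-on. The BRAF-off array helped to choose these genes and is shared by all 5, so this is not independent support.

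Known outputs of the ERK pathway, which BRAF feeds, were slightly higher as a group. Of 25 measured members, 3 were at least 2-fold higher (the phosphatase gene Dusp5 with a log2 ratio of 1.70, Fosl1 with 1.27 and Lif with 1.23) and none was that much lower. The median log2 ratio was 0.11, at the 99.8th percentile of 10000 random lists matched on level. Matrix proteases and their inhibitors had 5 of 19 members at least 2-fold higher, among them Adam8 (log2 ratio 1.65), and a median of 0.34. Secreted inflammatory factors had 5 of 20 higher and a median of 0.30. These were the chemokine genes Ccl2 (1.27) and Ccl5, and Lif, Mmp3 and Mmp13. Lif is also in the ERK list and Mmp3 and Mmp13 in the protease list, so these list results are not separate. Interferon response genes had no member past 2-fold, yet 29 of 33 lay above 0 with a median of 0.31, led by Oasl1 (0.81) and Psmb8 (0.77). Glycolysis and hypoxia genes had a median of 0.13 and endothelial markers, over 7 measured members, one of 0.42.

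Pigment cell genes were lower with BRAF activation. Of 27 measured members, 24 lay below 0, with a median log2 ratio of -0.50. Tyr, the tyrosinase that starts melanin synthesis, and the melanosome transporter gene Oca2 were both at -1.05. Schwann and glial markers, a list that shares Sox10 with the pigment list, had a median of -0.42 with 12 of 13 below 0. Cholesterol and fatty acid synthesis genes had 26 of 27 below 0 and a median of -0.25, led by Idi1 (-0.67) and Mvd (-0.62). S phase genes had a median of -0.10 and mesenchymal markers one of -0.07. Raising the floor to the 60th percentile of all values left 44 genes higher and 19 lower, so most of these calls came from dim genes. In simulated arrays with 200 changed genes, 129 of the unchanged genes were called in this comparison. The simulated spread came from BRAF-off and the array labelled ZEB2, a pair that differs in BRAF activation too. That count therefore cannot tell how many of the calls are noise. With 1 array per group, single genes near 2-fold carry little weight. The endothelial median no longer stood apart with the floor at the 60th percentile (0.25), and the mesenchymal one no longer did under 5 of the 9 alternatives.

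**Figure D1:**
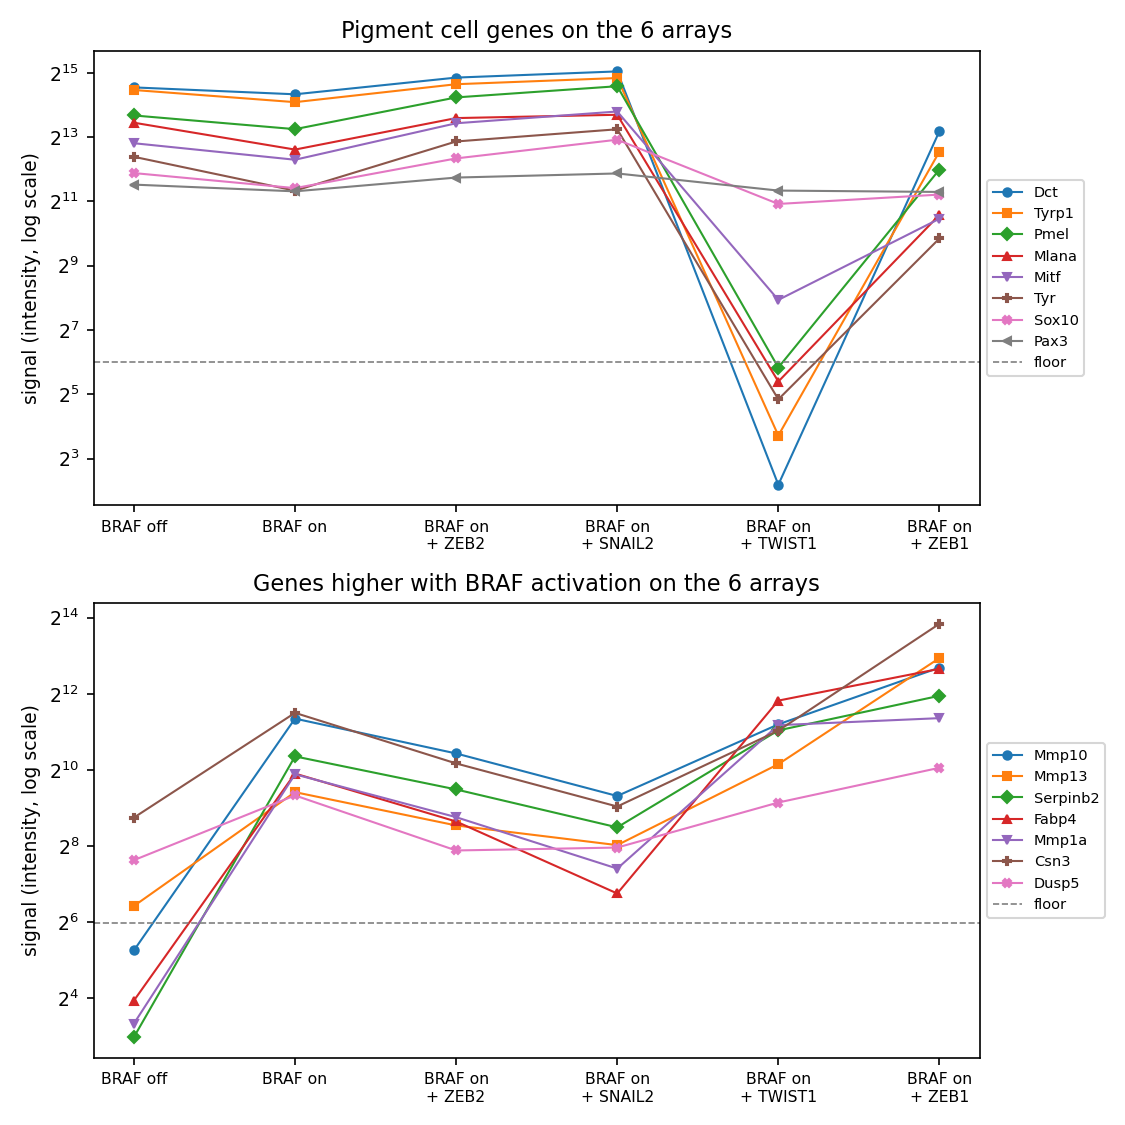
Signal (intensity, logarithmic axis) of pigment cell genes (top) and of genes higher with BRAF activation (bottom) on each of the 6 arrays, 1 point per gene and array, with the floor of 63.7 as a dashed line. Dct, Tyrp1, Pmel, Mlana and Tyr lie under the floor on the array labelled TWIST1, where Sox10 and Pax3 stay near their BRAF-on level.

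The array labelled ZEB2 had higher pigment cell genes than BRAF-on. In the array labelled ZEB2, 13 of 27 members were at least 2-fold higher than in BRAF-on and 26 lay above 0, with a median log2 ratio of 0.99. Oca2 stood at 1.70, Gpr143, Tyr and Slc45a2 each at 1.53, and Mitf, the regulator of melanocyte differentiation, at 1.14. Among the other genes on the higher side were Cfap54 (4.78-fold), Kcnj13 (4.34-fold), the lipase gene Mgll (3.82-fold) and the nuclear receptor gene Nr4a3 (3.44-fold). Among those on the lower side were the myosin light chain gene Myl9 (3.38-fold), Atp5md (2.90-fold), Dusp5 (2.72-fold), the cytokine gene Il6 (2.52-fold), Csn3 (2.51-fold) and the chemokine gene Cxcl10 (2.44-fold).

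All 27 measured genes of cholesterol and fatty acid synthesis were above 0 in the array labelled ZEB2, with a median of 0.78, and Idi1 (1.27) and Nsdhl (1.09) passed 2-fold. Lysosome and autophagy genes had a median of 0.24 and Schwann and glial markers one of 0.37, with S100b at 1.64 and Erbb3 at 1.08. Interferon response genes were lower, with 31 of 33 below 0 and a median of -0.39, and so were secreted inflammatory factors, with 4 of 19 at least 2-fold lower and a median of -0.30. With BRAF activation these lists had gone the other way (0.31 and 0.30), as had Schwann and glial markers (-0.42) and cholesterol synthesis (-0.25). Both comparisons share the single BRAF-on array, and these lists were not set against BRAF-off, so their directions may rest on that array. The TGF-beta response list had a median of -0.25, with Id1 at -1.01. Epithelial adhesion genes had a median of 0.33 over 10 members. Without a floor neither of these 2 lists stood apart, with medians of -0.04 for TGF-beta response and -0.000701 for epithelial adhesion. Together 199 of 11322 genes were at least 2-fold higher and 66 lower. With 3-fold as the size that counts, 25 and 1 were left.

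The array labelled SNAIL2 had the same direction in pigment cell genes as that labelled ZEB2, and more genes apart from BRAF-on. In the array labelled SNAIL2, 22 of 27 pigment cell genes were at least 2-fold higher than in BRAF-on and none was that much lower, with a median log2 ratio of 1.47. Oca2 was at 2.66, Gpr143 at 2.44, Mlph, a melanosome transport gene, at 2.32, Tyr at 1.91, Sox10 at 1.51 and Mitf 2.83-fold higher. The sphingosine phosphate receptor gene S1pr3 was 10.9-fold higher, Cfap54 8.48-fold, Mgll 7.09-fold, Kcnj13 6.76-fold and Nr4a3 6.60-fold. On the lower side were Nbeal1 (12.1-fold), Ccdc88a (10.9-fold), the nucleic acid sensor gene Zbp1 (10.2-fold), the kinetochore genes Cenpe (10.2-fold) and Cenpf (9.64-fold), Fabp4 (8.87-fold) and the chromatin remodeller gene Atrx (8.51-fold). In all, 641 of 11416 genes were at least 2-fold higher and 733 lower.

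Cholesterol and fatty acid synthesis genes had 15 of 27 members at least 2-fold higher in the array labelled SNAIL2, with a median of 1.05; Mvd was at 1.79, Dhcr7 at 1.71 and Fasn at 1.57. Lysosome and autophagy genes had a median of 0.46, with Npc1 at 1.37. Interferon response genes had 10 of 33 at least 2-fold lower, 32 below 0 and a median of -0.69, with Gbp3 at -1.61 and Ifit3 at -1.44. Secreted inflammatory factors had 6 of 20 lower and a median of -0.61, with Ccl2 at -2.23 and Cxcl10 at -1.60. Matrix proteases and inhibitors had a median of -0.34, though their members went both ways: Mmp10 (-2.03), Serpinb2 (-1.86) and Timp1 (-1.58) were lower, while Hpse (2.31) and Mmp2 (1.65) were higher. Mitosis genes had a median of -0.34 with 4 of 33 lower, the cell division marker Mki67 (-1.77) and Hmmr (-1.19) among them, and S phase genes had a median of 0.20. Ribosomal protein genes had a median of -0.31. The ribosomal median did not stand apart with quantile normalization (-0.11), and the protease median did not there (-0.27), with the median of all probe sets (-0.23) or without a floor (-0.08). Poly-A control transcripts added to the RNA before amplification were 2.44-fold higher on this array than on BRAF-on, and on all 24 of their probe sets.

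The array labelled TWIST1 had lower pigment cell genes than BRAF-on, 12 of them under the floor. In the array labelled TWIST1, Dct was at least 324-fold lower than in BRAF-on, Tyrp1 at least 274-fold, Pmel at least 153-fold and Mlana at least 98.4-fold. Dct and Tyrp1 encode melanin enzymes, Pmel the fibril protein of melanosomes and Mlana another melanosome protein. Mitf was 20.6-fold lower, at a signal of 245 against 5036. Of 26 measured members, 18 were at least 2-fold lower and none was that much higher, with a median log2 ratio of -2.76. Among the other members, the lineage transcription factor genes Pax3, at 2589 against 2546, and Sox10, at 1941 against 2730, stayed within 2-fold, and Gpnmb, though lower, was still at 2527. Tmsb4x, which encodes an abundant actin-binding peptide and has 1 probe set here, was at least 125-fold lower.

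Mesenchymal and fibroblast genes were higher in the array labelled TWIST1. Mesenchymal markers had 12 of 29 members at least 2-fold higher and a median of 0.72, and fibroblast markers, which share several members with them, had 8 of 15 and a median of 1.20. The matrix gene Fmod was 15.3-fold higher, Cnmd 10.9-fold, the surface protease gene Fap 7.22-fold, the smooth muscle gene Cnn1 6.16-fold and Postn 5.81-fold. Dcn was at 1.92 and Tagln at 2.04. All 33 interferon response genes were above 0 with a median of 0.68, 9 of them past 2-fold, including Zbp1 (1.88) and Oasl1 (1.74). Secreted inflammatory factors had 7 of 21 higher and a median of 0.72, with Ccl7 at 1.89. All 31 S phase genes were below 0, with a median of -0.35 and E2f2 at -1.25, and mitosis genes had a median of -0.12. ERK pathway output had a median of -0.21, with Myc at -1.13 and Dusp4 at -1.02, glycolysis and hypoxia genes one of -0.13 and cholesterol and fatty acid synthesis genes one of -0.19, which at -0.15 with the median of all probe sets no longer stood apart. In all, 230 of 11334 genes were at least 2-fold higher and 229 lower. Matrix proteases and inhibitors had a median of 0.21, which turned to -0.10 without a floor.

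The array labelled ZEB1 had lower cell cycle genes than BRAF-on. In the array labelled ZEB1, 24 of 31 S phase genes and 23 of 33 mitosis genes were at least 2-fold lower than in BRAF-on, and all members of both lists were below 0, with medians of -1.19 and -1.17. Ccne2 was at -2.14, the replication genes Cdc6 and Mcm2 at -2.10 and -1.88, Mki67 at -2.41 and Cenpf at -2.26. Cell cycle inhibitors and p53 targets had 7 of 28 members higher, among them Cdkn1c (1.67), Gadd45a (1.38), Cdkn1a (1.31) and Cdkn2b (1.04), and 2 lower, Lmnb1 (-1.56) and Aen (-1.28). That list as a whole, with a median of 0.25, did not stand apart from random lists. Pigment cell genes had 12 of 26 members lower and a median of -0.99, with Trpm1 at -2.32, Kit at -2.28, Mitf at -1.84 and Dct at -1.15.

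Of the matrix proteases and inhibitors at least 2-fold higher with BRAF activation, Mmp13 (11.5-fold above BRAF-on), Mmp3 (7.08-fold), Serpinb2 (log2 ratio 1.59) and Mmp10 (1.34) were that much higher again in the array labelled ZEB1, and Adam8 (0.76) was not. That list had 5 of 20 members higher and 2 lower, Adam12 at -1.41 and Hpse at -1.27 (a bound), with a median of 0.56. Inmt, a methyltransferase gene, was 12.7-fold higher, Mustn1 12.3-fold, the lipid carrier gene Apoe by a log2 ratio of 3.25 and Fabp4 6.73-fold. All 33 interferon response genes were above 0, with 12 past 2-fold and a median of 0.79, led by Irf7 (1.96). All 7 measured macrophage and leukocyte markers were above 0 too, with a median of 0.64 that did not stand apart. Whether these rises share a source was not tested. Secreted inflammatory factors had a median of 0.55, with Ccl5 at 1.66 while Il6 was at -1.31. Lysosome and autophagy genes had 29 of 30 above 0 and a median of 0.54, and apoptosis regulators a median of 0.29, with Bcl2l11 at 1.56 and Bmf at 1.35. Fibroblast markers had a median of 0.48, keratinocyte markers one of 0.51 and cholesterol and fatty acid synthesis genes one of -0.20. Without a floor the fibroblast (0.32) and keratinocyte (0.55) medians did not stand apart, and with the median of all probe sets the cholesterol (-0.18), apoptosis (0.20) and keratinocyte (0.51) medians did not. Mesenchymal markers went both ways, with a median of 0.13 that did not stand apart: Tagln (5.74-fold), Ccn2 (-1.71), Ccn1 (-1.45) and Acta2 (-1.38) were lower, and Bgn (1.87), Fap (1.84) and Col6a1 (1.62) were higher. In all, 522 of 11614 genes were at least 2-fold higher and 456 lower. With 3-fold as the size that counts, 112 and 85 were left.

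**Figure D2:**
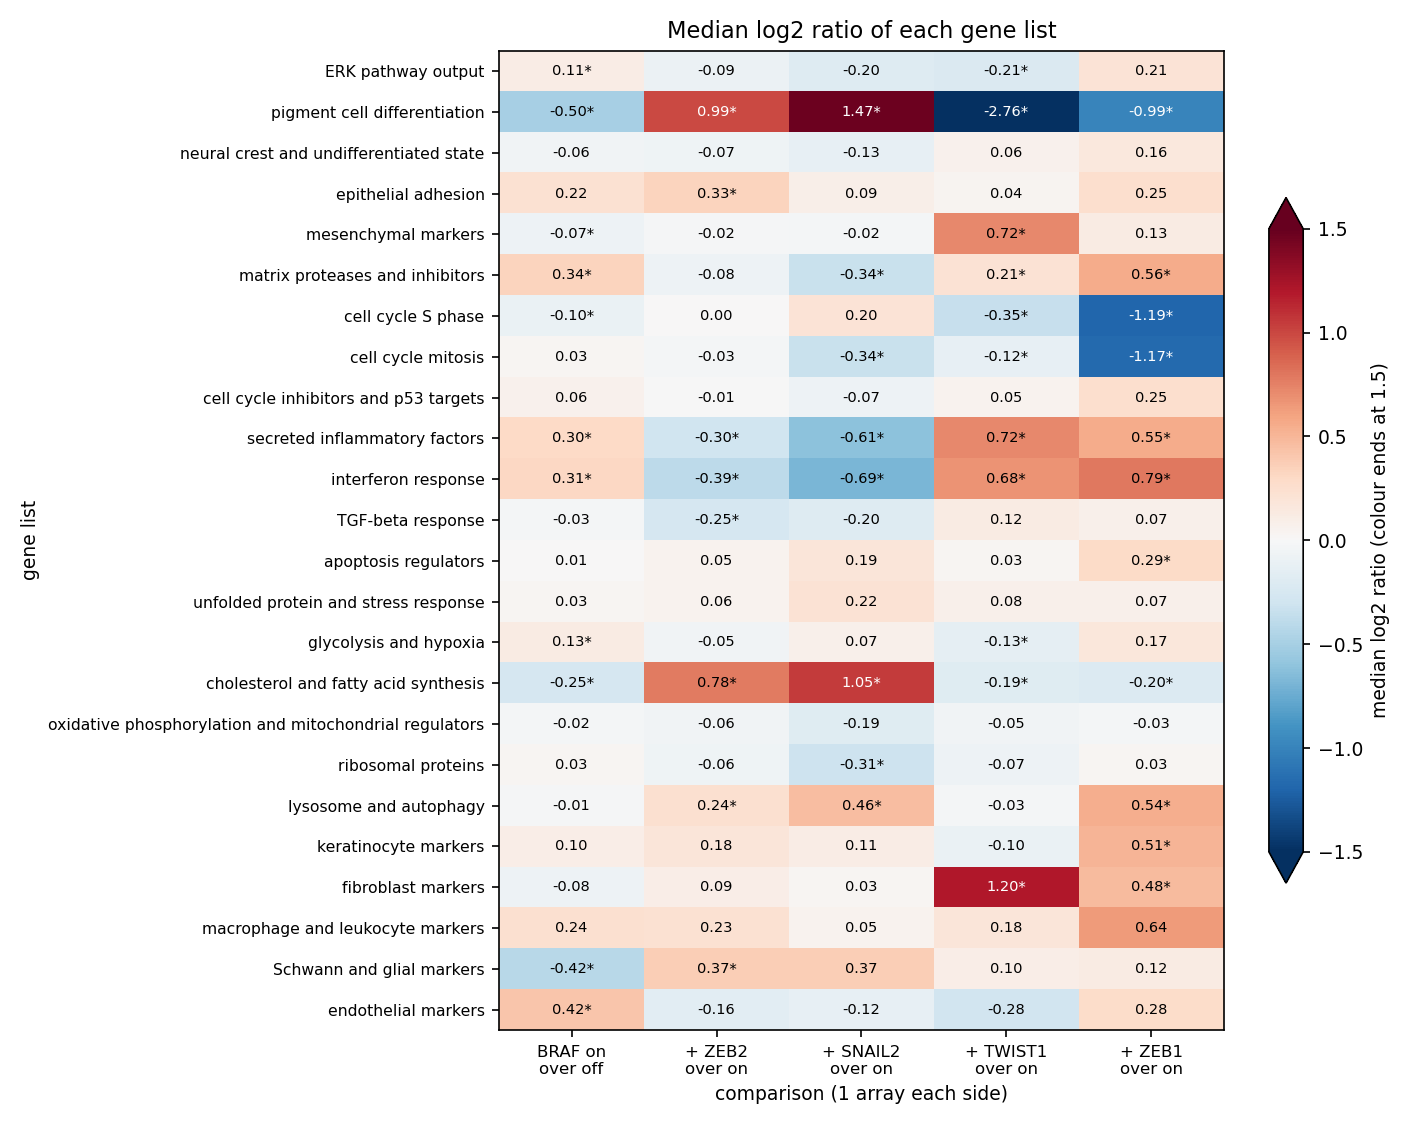
Median log2 ratio of each gene list (rows) in each comparison (columns), with an asterisk where the median lay outside the central 95% of 10000 random lists matched on level. Pigment cell genes range from -2.76 in the array labelled TWIST1 to 1.47 in the array labelled SNAIL2.

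The study asked how each factor bears on genes that respond to BRAF. Of the 116 genes higher with BRAF activation, 62 were at least 2-fold lower than BRAF-on in the array labelled SNAIL2 (53.4%). The array labelled ZEB2 had 28 such genes (24.1%), that labelled TWIST1 12 (10.3%) and that labelled ZEB1 2 (1.72%). Of all genes compared with BRAF-on, 6.42% were that much lower with SNAIL2, 0.583% with ZEB2, 2.02% with TWIST1 and 3.93% with ZEB1. Fabp4 (8.87-fold), Mmp1a (5.56-fold), Csn3 (log2 ratio -2.46), Ccl2 (4.69-fold) and Ifi213 (4.81-fold) were lowered most in the array labelled SNAIL2. In the array labelled ZEB1, 41 of the 116 were instead at least 2-fold higher still, and in that labelled TWIST1 9 were. The median share of the BRAF difference left was 29.1% with SNAIL2, 52.3% with ZEB2, 92.8% with TWIST1 and 149% with ZEB1. Of the 43 genes lower with BRAF activation, 24 were at least 2-fold back up with SNAIL2, 22 with ZEB2, 12 with TWIST1 and 7 with ZEB1. Going at least 2-fold further down were 1 with SNAIL2, 0 with ZEB2, 10 with TWIST1 and 8 with ZEB1. Of all genes compared with BRAF-on, 5.61% were at least 2-fold higher with SNAIL2, 1.76% with ZEB2, 2.03% with TWIST1 and 4.49% with ZEB1. Cfap54, Mgll and Kcnj13 were among the genes back up in the arrays labelled SNAIL2 and ZEB2, and Fmod and Cnmd in that labelled TWIST1. These genes were chosen with the BRAF-on array, so chance alone moves them back in every other array. By percent moved back, SNAIL2 came first for the higher genes under 8 of the 9 alternatives. Without a floor TWIST1 had 43.8% and SNAIL2 42.3%. The full order of the 4 factors held under 5 alternatives for the higher genes and under 3 for the lower ones. This order does not allow for the shares over all genes, which were also highest with SNAIL2 and were lowest with ZEB2. As a multiple of its share, ZEB2 came first for the higher genes (24.1% against 0.583%). It also did for the lower ones (22 of 43 against 1.76%). ZEB1 lay below its share for the higher genes (1.72% against 3.93%).

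Pairs of factors shared genes apart to different extents. The arrays labelled ZEB2 and SNAIL2 had 170 higher genes in common, against 11.1 for independent lists and 6.63 for simulated unchanged arrays sharing BRAF-on, and 48 lower genes in common, against 4.33 and 29.1. Those labelled TWIST1 and ZEB1 had 92 higher genes in common, against 9.59 and 6.95, and 82 lower, against 9.31 and 29.5. Those labelled SNAIL2 and ZEB1 had 80 lower genes in common, against 29.9 and 29.1, and 44 higher, against 26.0 and 6.74, but 58 genes higher with SNAIL2 were lower with ZEB1 (24.8 for independent lists) and 59 the other way (31.2). Also in opposite directions, 103 genes higher with SNAIL2 were lower with TWIST1, against 12.5 for independent lists. Across genes, which are not independent replicates, the covariance of log2 ratios was 0.186 for ZEB2 and SNAIL2 and 0.119 for TWIST1 and ZEB1, against 0.0581 and 0.0582 in the simulation. The correlation was 0.744 for the first pair and 0.416 for the second, against 0.531 for both in the simulation. For SNAIL2 and ZEB1 the correlation was 0.0827 and the covariance 0.0316, both below the simulated 0.531 and 0.0581. ZEB2 with TWIST1, ZEB2 with ZEB1 and SNAIL2 with TWIST1 had 7, 6 and 16 lower genes in common. The simulation gave 29.2, 29.2 and 29.6. Higher genes in common there were 4, 19 and 10, against 6.75, 6.66 and 6.82. Their correlations were -0.167, 0.00789 and -0.208, against 0.53 in the simulation. The simulation can thus overstate what sharing BRAF-on gives, and its values are a rough yardstick. The single BRAF-on array could not be split, so part of the excess in other pairs may come from that array. By pairs of arrays, BRAF-off and the array labelled ZEB2 had 149 genes apart and BRAF-off and BRAF-on 159, while the arrays labelled SNAIL2 and TWIST1 had 2176.

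**Figure D3:**
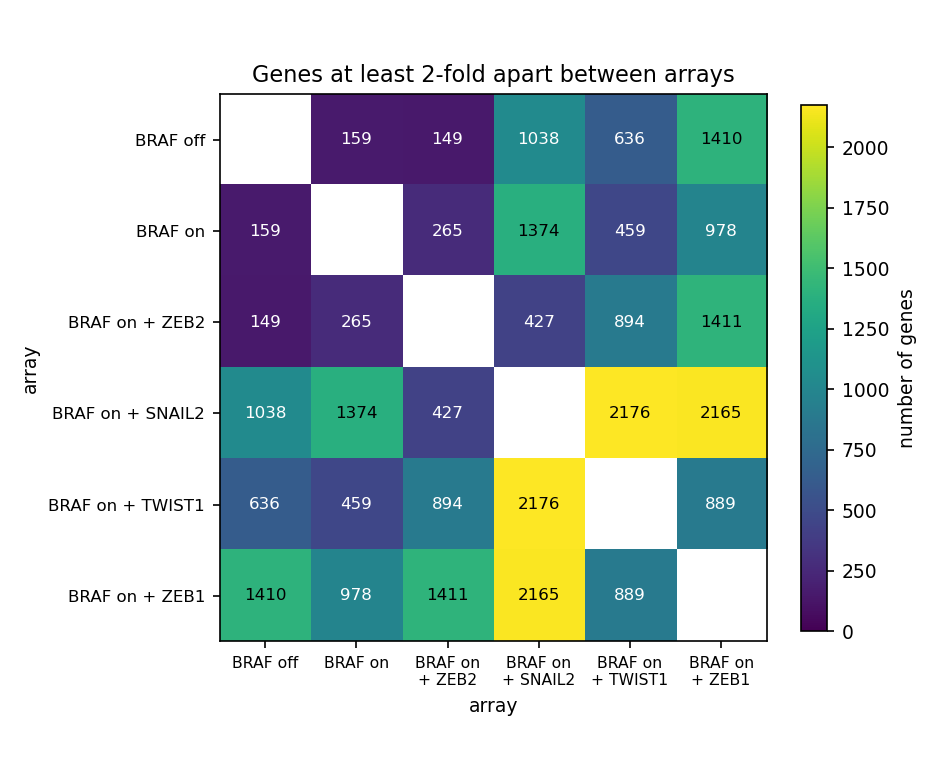
Number of genes at least 2-fold apart for each of the 15 pairs of arrays (both axes list the 6 arrays, colour and printed number give the count). The counts run from 149 for BRAF-off and the array labelled ZEB2 to 2176 for the arrays labelled SNAIL2 and TWIST1.

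The lists without a median apart from random lists in any comparison were neural crest and undifferentiated state, cell cycle inhibitors and p53 targets, unfolded protein and stress response, oxidative phosphorylation and mitochondrial regulators, macrophage and leukocyte markers, and the introduced factors. Over 125 pairs of list and comparison, 49 medians stood apart, where 6.25 would by chance if genes moved independently. Genes of a list can move together, some lists share members, and every comparison uses the BRAF-on array. The 6.25 is therefore not the number that ordinary differences between cultures would give. Cdh1, the epithelial cadherin that these factors are known to repress, was under the floor on all 6 arrays, and 10 to 12 of the 35 epithelial adhesion genes entered any comparison.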

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

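All tests in this part were chosen after the results were seen, except those on scaling and on probe sets at lower signals. For 5 gene lists, the medians against BRAF-on stood apart in opposite directions in different factor arrays; these differences were not tested, since each group has 1 array.

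Pigment cell genes were higher in the arrays labelled ZEB2 and SNAIL2 and lower in those labelled TWIST1 and ZEB1. The median log2 ratio was 1.47 with SNAIL2 and -2.76 with TWIST1, which is 4.23 apart. The gap between factor arrays does not involve BRAF-on. Compared directly, pigment genes had a median log2 ratio of 4.81 for SNAIL2 over TWIST1 and 2.10 for ZEB2 over ZEB1. An unusual BRAF-on array could set only which factor arrays lie above or below it. Against BRAF-off, the smaller of the ZEB2 and SNAIL2 medians was 0.48, where ZEB2 over BRAF-on had 0.99. The median nearer to 0 of TWIST1 and ZEB1 was -1.47. Both directions held, which argues against BRAF-on as their only source. Part of the ZEB2 rise may still come from that array. Under quantile normalization or centring the smallest of the 4 medians, each in its direction, was still 0.95, which argues against scaling. Probe sets for 18S ribosomal RNA split alike, at 0.480 of BRAF-on with TWIST1, 0.565 with ZEB1, 1.34 with ZEB2 and 1.06 with SNAIL2. With SNAIL2 only 2 of the 3 were above BRAF-on. Whether a difference between the RNA samples bears on the pattern was not tested. That the factors act in opposite ways on this program may be a biological explanation, as a hypothesis from 1 array each. A wrong label or a difference between cultures stays open.

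The pigment enzymes under the floor with TWIST1 are a pattern of their own. Replacement of the melanocytes by other cells would have taken Sox10 and Pax3, which mark the same lineage, down with Dct. The lower of their log2 ratios was -0.49, which argues against that unless the other cells express both. Fibroblasts are a candidate source, since 8 of 15 fibroblast markers were higher. Of the 10 fibroblast markers under the floor in BRAF-on, Pdgfra (105) and Thy1 (96.6) crossed it with TWIST1 and 0 reached 3 times the floor, and Col1a2, abundant in fibroblasts, was at 146 against 161 in BRAF-on. This marker set replaced 7 genes picked by hand after their levels were known, and the limit of 3 times was also set after, so the test weighs less than its count. A response of the melanocytes themselves stays open as a hypothesis.

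More genes were apart with SNAIL2 than with any other factor, 1374 in all. The poly-A spike-ins, control probe sets outside the comparisons, were 2.44-fold above BRAF-on there, and 1.76-fold above the next highest factor array. Hybridization spike-ins were 1.21-fold above BRAF-on, on all 18 of their probe sets. Ratios of 3' to 5' control probe sets were near those of BRAF-on, at 0.839 against 0.811 for Gapdh and 1.44 against 1.47 for Actb. Noise of single probe sets would leave the probe sets of 1 gene unlike each other. At signals of 200 or more on both arrays, where 910 of the 1374 genes lay, they shared 76.6% of the variance of log2 ratios, against 35.4% for BRAF activation. From the floor up to that signal, with 356 of the genes, they shared 62.0%, against 19.5%. This argues against such noise as the whole cause there, although the spread within genes was also the largest of the 5 comparisons (SD of log2 ratios 0.287 at the higher signals and 0.472 at the lower). The 108 genes with 1 array under the floor were not covered, nor were genes with 1 probe set. The RNA amount or its amplification and an effect of SNAIL2 cannot be told apart, since this array alone is labelled with that factor. By both spike-ins and genes apart ZEB1 came second, with 1.39-fold and 978 genes, but ZEB2 (1.33-fold, 265 genes) and TWIST1 (0.879-fold, 459 genes) ranked in opposite order.

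Interferon response genes had a median of 0.79 with ZEB1 and -0.69 with SNAIL2, 1.48 apart. Secreted inflammatory factors were 1.33 apart between TWIST1 and SNAIL2. Cholesterol and fatty acid synthesis genes were 1.25 apart between SNAIL2 and ZEB1, and matrix proteases and inhibitors 0.90 apart between ZEB1 and SNAIL2, although the SNAIL2 median did not stand apart under 3 of the 9 alternatives and was -0.08 without a floor. Unlike the pigment list, these lists were not set against BRAF-off, so their directions hold only relative to the BRAF-on array. Among probe sets with no gene or several, which no comparison used, 9 were at least 2-fold above both BRAF-off and BRAF-on with ZEB2, 76 with SNAIL2, 34 with TWIST1 and 89 with ZEB1.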

How the results depend on the processing

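The comparison with BRAF-off was chosen after seeing the data; the 9 other alternatives were planned. No paired analysis was possible because each group has 1 array. Quantile normalization, centring and leaving out probe sets that match several transcripts kept all 10 counts within 1.5 times. Of the 49 list medians that stood apart, 37 did so in the same direction under all 9 alternatives, and none stood apart in the other direction. The 12 that did not throughout were mesenchymal and endothelial markers with BRAF activation, epithelial adhesion and TGF-beta response with ZEB2, matrix proteases and ribosomal proteins with SNAIL2, matrix proteases and cholesterol synthesis with TWIST1, and apoptosis regulators, cholesterol synthesis, keratinocyte and fibroblast markers with ZEB1; the size that counts cannot move a median. The matrix protease median with TWIST1 turned to -0.10 without a floor and to -0.0298 with the median of all probe sets, and the epithelial median with ZEB2 to -0.000701 without a floor. With the median of all probe sets, Casp9 (-0.43), Idh3a (0.0397) and Trp53inp1 (-0.49) turned with SNAIL2. Lists with fewer than 5 members left under a higher floor gave no value. Raising the floor removes dim genes by construction, leaving it out lets in values near background, and a larger size leaves fewer genes. The spread between cultures is not measured with 1 array per group. The cause of the other shifts was not tested.

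With the floor at the 60th percentile, 44 genes were higher and 19 lower with BRAF activation, 30 lower with ZEB2, 148 lower with TWIST1, and 67 apart between BRAF-off and ZEB2, while BRAF-off and BRAF-on had 63. With the floor at the 75th percentile, the higher and lower counts were 15 and 6 for BRAF activation, 65 and 11 for ZEB2, 323 and 390 for SNAIL2, 73 and 48 for TWIST1, and 192 and 232 for ZEB1; 19 genes were apart between BRAF-off and ZEB2 and 1126 between SNAIL2 and TWIST1. Without a floor they were 2584 and 1161 for BRAF activation, 1717 and 1812 for ZEB2, 2240 and 2679 for SNAIL2, 1628 and 2467 for TWIST1, and 2298 and 2029 for ZEB1, with 3660 and 5878 apart in those pairs. With the floor as a pseudocount, 21 were lower with BRAF activation, 121 higher and 26 lower with ZEB2, 341 higher with ZEB1, and 85 apart between BRAF-off and ZEB2. With the median of all probe sets, 100 were lower with ZEB2. At 3-fold the counts were 41 and 5 for BRAF activation, 25 and 1 for ZEB2, 155 and 176 for SNAIL2, 72 and 81 for TWIST1, and 112 and 85 for ZEB1, with 24 and 742 apart in the pairs. Against BRAF-off, 113 were higher and 36 lower with ZEB2, 346 higher with TWIST1 and 812 higher with ZEB1.

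The percent of genes higher with BRAF activation that moved back was 63.6% with SNAIL2 and 0% with ZEB1 at the 60th percentile floor, and 66.7% with SNAIL2 and 0% with TWIST1 and ZEB1 at the 75th. Without a floor it was 38.0% with ZEB2, 42.3% with SNAIL2, 43.8% with TWIST1 and 32.5% with ZEB1. With the floor as a pseudocount it was 9.18% with ZEB2 and 34.7% with SNAIL2; with the median of all probe sets, 20.4% with TWIST1 and 9.15% with ZEB1; at 3-fold, 0% with ZEB2, 2.44% with TWIST1 and 0% with ZEB1. For genes lower with BRAF activation it was 5.26% with ZEB1 at the 60th percentile floor, 83.3% with ZEB2 and 0% with TWIST1 and ZEB1 at the 75th, 53.4% with TWIST1 and 58.9% with ZEB1 without a floor, 34.0% with ZEB1 with the median of all probe sets, and 20% with ZEB2, 20% with SNAIL2 and 0% with TWIST1 at 3-fold. The order of the factors changed in several places. For the higher genes TWIST1 was above SNAIL2 without a floor and above ZEB2 at 3-fold, with the pseudocount (10.2%) and without a floor. For the lower genes ZEB2 was above SNAIL2 at the 75th percentile floor (66.7% with SNAIL2) and with the pseudocount (47.6% and 42.9%), and ZEB1 was above TWIST1 with the median of all probe sets (26.4% with TWIST1), without a floor, where it was also above ZEB2 (56.8%), and at 3-fold (20% with ZEB1). At 3-fold ZEB2, SNAIL2 and ZEB1 were level, as were ZEB2 and SNAIL2 at the 60th percentile floor. The genes lower with BRAF activation numbered 19 at the 60th percentile floor and 6 at the 75th. They numbered 21 with the pseudocount and 5 at 3-fold, so very few genes decide the order in these settings.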

Other observations

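Of the tests in this part, the one on the neighbours of Tmsb4x was set before its result was seen, and the one on ERK output with ZEB2 took its final form after. The list of macrophage and leukocyte markers had 7 measured members in the array labelled ZEB1, all above their BRAF-on level. Cd53 (5.59-fold) and Cd68 (log2 ratio 1.87) passed 2-fold, and the median log2 ratio of 0.64, at percentile 97.3 of random lists, did not stand apart. Among the largest rises outside this list were Mpeg1 (6.47-fold), Plac8 (5.72-fold) and S100a8 (at least 5.35-fold). Whether other cells were present in that culture was not tested.

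Genes of the undifferentiated state went both ways in the array labelled TWIST1. Nt5e (1.85, a lower bound), Wnt5a (1.81) and Aldh1a1 (1.52) were higher, and Nes (-1.41) and Id2 (-1.21) were lower. The insulin-like growth factor binding protein genes Igfbp2 and Igfbp5 were at least 5.77-fold and at least 4.97-fold higher, and the peripheral myelin gene Pmp22 was 5.64-fold higher. Probe sets for 18S ribosomal RNA were at 0.480 of BRAF-on with TWIST1 and 0.565 with ZEB1.

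Tmsb4x, at a signal of 7952 in BRAF-on and 17.3 in the array labelled TWIST1, prompted the hypothesis that its chromosome segment was lost in those cells. The nearest measured neighbours by the RefSeq order, Tceanc and Prps2, had log2 ratios of 0.21 and 0.35, which argues against a loss reaching them. A loss of the gene alone, silencing, or a failure of its 1 probe set may each remain, and none was tested.

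The array labelled ZEB2 had fewer genes apart from BRAF-off (149) than from BRAF-on (265), which prompted the hypothesis of less output of the activated BRAF there. Without a floor it was no nearer to BRAF-off, with 3660 genes apart from it and 1717 higher and 1812 lower than in BRAF-on. The ERK output list had a median log2 ratio against BRAF-off of 0.13 with ZEB2 and 0.11 in BRAF-on, with 18 of 25 members above 0 in both. Against BRAF-on the list had a median of -0.09 with ZEB2, with 10 members above 0 and 15 below. Dusp5 was at 198 in BRAF-off, 644 in BRAF-on and 236 with ZEB2, and Lif at 218, 511 and 235. Fosl1, the other member at least 2-fold higher with BRAF activation, was not 2-fold lower with ZEB2. These genes were chosen with the BRAF-on array, so chance alone moves them back. The difference between the medians of 0.13 and 0.11 was small against the spread over members, so the test could not decide.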
